A study of Homo sapiens with 20 samples.

How the data were processed

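Chromatin immunoprecipitation and sequencing of 3 histone marks was carried out by the authors in H1 cells, an established human embryonic stem cell line. Per the labels' protocols, cells were transduced with lentiviral vectors carrying a short hairpin RNA, selected with puromycin and expanded before fixation, sonication and immunoprecipitation. The marks were H3K9me3, found in heterochromatin and at silenced repeats, H3K27ac, found at active promoters and enhancers, and H3K4me1, found at enhancers. Each mark had 5 libraries: shLuc A and B, shZNF587 A and B, and a single shE library. The series' description speaks of control hairpins and of hairpins against ZNF417 and ZNF587. shLuc was taken as the control and shZNF587 as the hairpin treatment. The labels do not say what shE targets, so it was kept as a group of its own. The 5 input samples had no peak list among the files used here, and reads were not analysed here.

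The deposited files were 15 peak lists, called by the authors for each library separately. Bowtie2 and the hg19 genome build are named in the submitters' processing notes, without versions. The peak caller, its settings and the treatment of duplicate reads are not given in the sources used here. Each line of a deposited list held a chromosome, a start, an end, a p-value or q-value and a score. The deposited p-value or q-value reached at most 0.0377 to 0.0500 in a list, and whether it had been adjusted is not given in the sources used here. The authors' score lay between 0 and 1000. Among scores strictly inside these limits, 99.8 to 100% were 100 times the log2 of a ratio of whole numbers with a denominator of at most 2000, within 1e-12. No scaling for sequencing depth was visible in that ratio, so scores were used only to rank peaks within a list. Scores of 0 made up to 25.6% of a list, in the H3K9me3 shE library, and up to 42 peaks of a list stood at the upper limit. All peak edges lay on a grid of 200 bp, peaks of a list did not overlap, and the smallest gap between neighbours was 800 bp. The lists held 0 columns of other samples.

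Read depth is unknown from peak lists. The number of peaks and the length they cover were therefore given for each library as the only measures of how much was called. A library with a shorter list can lack a peak because fewer reads were available, and the absence of a peak is not a measurement of no signal. Chromosome Y was left out, and chromosomes 1 to 22 and X were kept. Nothing in the labels says that libraries A and B came from separate cultures, so every comparison measures only the spread between these libraries, which may be technical. Tests over regions treat regions as units. They describe these libraries and not replicate cultures, and neighbouring regions are not independent.

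For each mark, the peaks of the 4 shLuc and shZNF587 libraries were merged into regions where they overlapped or touched. A library held a region when at least 1 bp of a peak lay in it. Regions held by both shZNF587 libraries and neither shLuc library were called gained, the opposite lost, and regions held by all 4 libraries kept. The 4 libraries can be divided into equal groups in 3 ways, so an exact permutation p cannot go below 0.333. The other 2 divisions gave the background: libraries B against libraries A, and the crossed division, shLuc A with shZNF587 B against shLuc B with shZNF587 A. Only the crossed division is, like the real one, balanced for the letters. In the crossed division, regions counted as gained were those of one fixed mixed pair, so its directions carry no biological meaning. Group values are means with standard deviations of 2 libraries, and their differences were tested by two-sided exact permutation. Jaccard indices are shared bases over united bases.

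Whether a changed region of one mark overlapped a changed region of another was compared with kept regions by a Mantel-Haenszel odds ratio, two-sided, over 5 strata of region length, because long regions overlap more by chance. The 5 pairs of marks were adjusted together by the Benjamini-Hochberg method. Odds ratios were not tested between divisions, and overlap of their intervals is no such test. Each of 23 chromosomes was tested by Fisher's exact test, two-sided, changed against kept regions, with Benjamini-Hochberg adjustment over 138 tests. Shares of regions with a shE peak have exact 95% binomial intervals, which cover counting error only. Whether neighbouring regions changed together was compared with 1000 shuffles of states within chromosome and length stratum.

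Regions are named by position, since no annotation of hg19 was used here and gene names of another build were not transferred. For that reason the tests of gene lists, with their alternative windows, were not run. For each mark and direction the 12 regions of best rank are named. A region's rank is the lower, over the 2 libraries that hold it, of the within-list percentile of its best peak by the authors' score. Loci changed in 2 marks are described by the same rank. Coordinates count from 1.

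The groups, tests, naming rule and most alternatives were chosen before the data were examined. The alternatives were presence only where peaks cover 50% of a region, merging across 1 kb, equal numbers of top peaks by score, the upper 50% of each list, bins of 1 kb, a shE library required to look like shLuc, a replicate block, unstratified tests, a distance of 5 kb between marks, and leaving out each library in turn. Further settings were added after seeing the data: regions whose peaks lay above the 50th or 75th percentile of both lists, equal numbers of top peaks by the p-value or q-value, peaks over 100 kb left out, peaks over 1 Mb left out, equal list lengths for the shE and chromosome results, and left-out libraries for the shE, Jaccard, covered length and chromosome results. Single chromosomes and the named regions were followed through all settings only after seeing the data as well. An exact conditional test over the length strata was added for the pairs of marks in the same way.

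Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The code was tested on simulated data. For the gained and lost H3K9me3 regions, 200 of 200 planted losses and 200 of 200 planted gains were recovered over 20000 regions. These were planted with exactly the pattern of presence that the rule calls. Their recovery checks the code and does not measure the sensitivity of the rule. For the pairs of marks, a planted odds ratio of 3 was estimated as 3.19 (95% interval 2.55 to 4.00) over 40000 regions.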

Results

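The series asked how chromatin of H1 embryonic stem cells differs when hairpins against ZNF417 and ZNF587 are expressed. Both are KRAB zinc finger proteins, a family that binds DNA and is known to bring H3K9me3 to its targets, many of which lie in transposable elements. Peak lists of H3K9me3, H3K27ac and H3K4me1 were compared between 2 control libraries (shLuc A and B) and 2 hairpin libraries (shZNF587 A and B) per mark. A single shE library per mark was looked up separately. The lists held 54592 to 147209 peaks outside chromosome Y, which covered 278 to 546 Mb. No expression values were analysed here, so the level of the hairpins' targets was not measured.

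**Figure D1:**
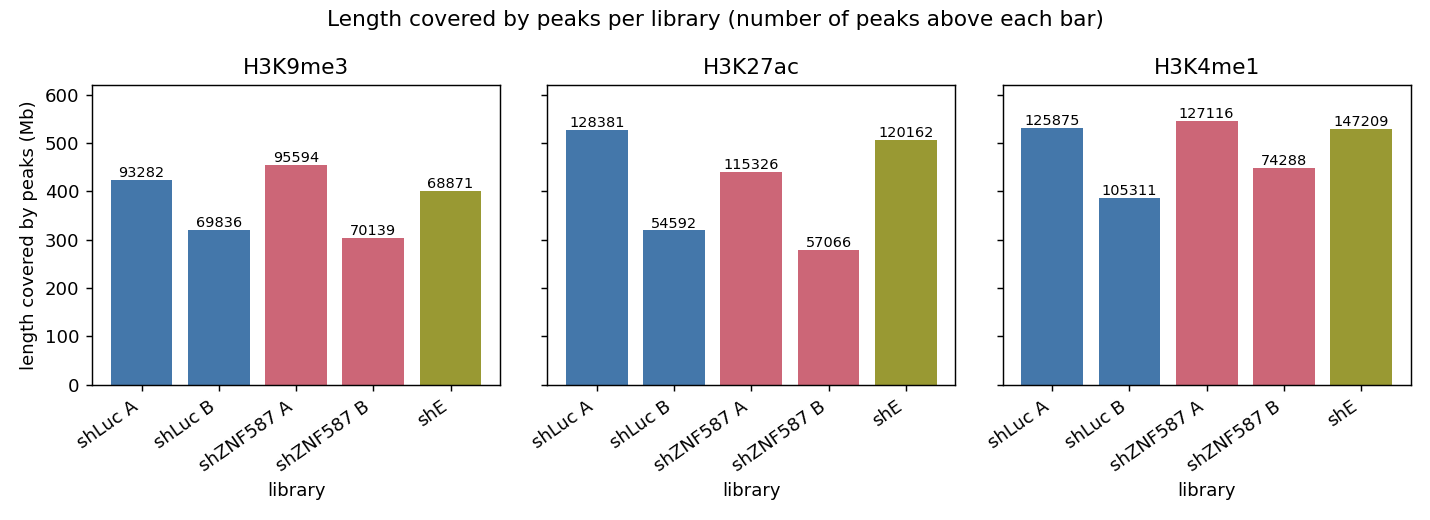
Length covered by peaks (Mb, bars) in each of the 15 libraries, with the number of peaks above each bar, for H3K9me3, H3K27ac and H3K4me1. In all 3 marks, libraries with the letter A cover more than libraries with the letter B of their group.

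H3K9me3 was called over a similar length in both groups, but its places differed. Peaks were lost in shZNF587 at 3318 regions, which was 6.53% of the regions held by both shLuc libraries, and gained at 3017 regions, 6.06% of those held by both shZNF587 libraries. Another 38039 regions were kept. Most lost regions had low-ranking peaks, with a median at percentile 24.8. Over all regions the more frequent direction depended on the setting: gains outnumbered losses with 50% of a region covered (4814 against 4104), in bins of 1 kb (18087 against 15807) and with shE required to look like shLuc (2575 against 2052). At high rank losses were more frequent, where rank follows the authors' score and does not measure how reliably a peak is called. At 269 regions both shLuc peaks ranked above the 75th percentile of their lists while neither shZNF587 library held a peak, against 55 regions in the opposite direction.

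The 12 lost H3K9me3 regions of best rank were short, 1400 to 3600 bp, and both shLuc peaks stood at or above percentile 97.9 of their lists. The first was on chromosome X at 27475801–27478200 (hg19), followed by chromosome 3 at 132188601–132191200, chromosome 15 at 62982201–62983600 and chromosome 22 at 27168601–27170000. The next were on chromosome 3 at 41346401–41348400, chromosome 5 at 61808801–61810200, chromosome X at 100227201–100230600 and chromosome X at 71096401–71098600. Chromosome 17 at 15769601–15772800, chromosome X at 69897201–69900000, chromosome 14 at 89971401–89975000 and chromosome X at 77519401–77522000 completed the set. All 12 held an H3K9me3 peak in the shE library. The rank favours chromosome X, which holds 5 of these 12 regions and 4 of the 12 gained ones, because peaks on X had a median percentile of 89.4 to 94.98 in every H3K9me3 list. Of the 12 gained regions of best rank, 2 held a shE peak, and their lower percentiles ranged from 88.9 to 97.8. They were led by chromosome X at 48497601–48498800, chromosome 22 at 49002801–49003600, chromosome 2 at 83164801–83166200 and chromosome X at 126528401–126532200.

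The background came from divisions of the same 4 libraries that ignored the hairpin. The crossed division, balanced for the letters A and B, gave 1558 and 1110 one-sided H3K9me3 regions, and 29 and 23 above the 75th percentile. Gained and lost regions together were thus 2.37 times as many under the real division (6335 against 2668). Dividing by letter gave 865 and 15908 regions, and 10 and 1857 above the 75th percentile, so the letter separated the lists far more than the hairpin did. Within letter A, 18379 regions were held by shZNF587 alone and 17447 by shLuc alone. Within letter B these were 16797 and 17048. Leaving out a library loosens the rule and leaves the letters unbalanced. Gained regions then numbered 10610 without shLuc A, 8994 without shZNF587 A and 15603 without shZNF587 B, and lost regions 7473 without shLuc A, 15588 without shLuc B and 12223 without shZNF587 A.

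The covered length of H3K9me3 was 372 ± 72.6 Mb in shLuc and 378 ± 107 Mb in shZNF587 (SD, n = 2 each), a difference well inside the spread between libraries (exact permutation p = 1, smallest possible 0.333). The difference of shZNF587 minus shLuc turned to −44.6 Mb without shLuc B and −68.9 Mb without shZNF587 A, and was 58.1 Mb without shLuc A and 82.5 Mb without shZNF587 B. The peak numbers were 81559 ± 16579 and 82867 ± 17999 (exact permutation p = 0.667, n = 2 each). Bases shared between lists gave Jaccard indices of 0.668 for shLuc A with shZNF587 A and 0.584 for shLuc B with shZNF587 B. Within groups, where the libraries differ in letter, they were 0.591 for the shLuc pair and 0.533 for the shZNF587 pair. Pairs that differ in both letter and group gave 0.523 for shLuc A with shZNF587 B and 0.556 for shLuc B with shZNF587 A. Between 4 and 6 H3K9me3 peaks per library exceeded 1 Mb, the widest reaching 20.1 Mb.

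**Figure D2:**
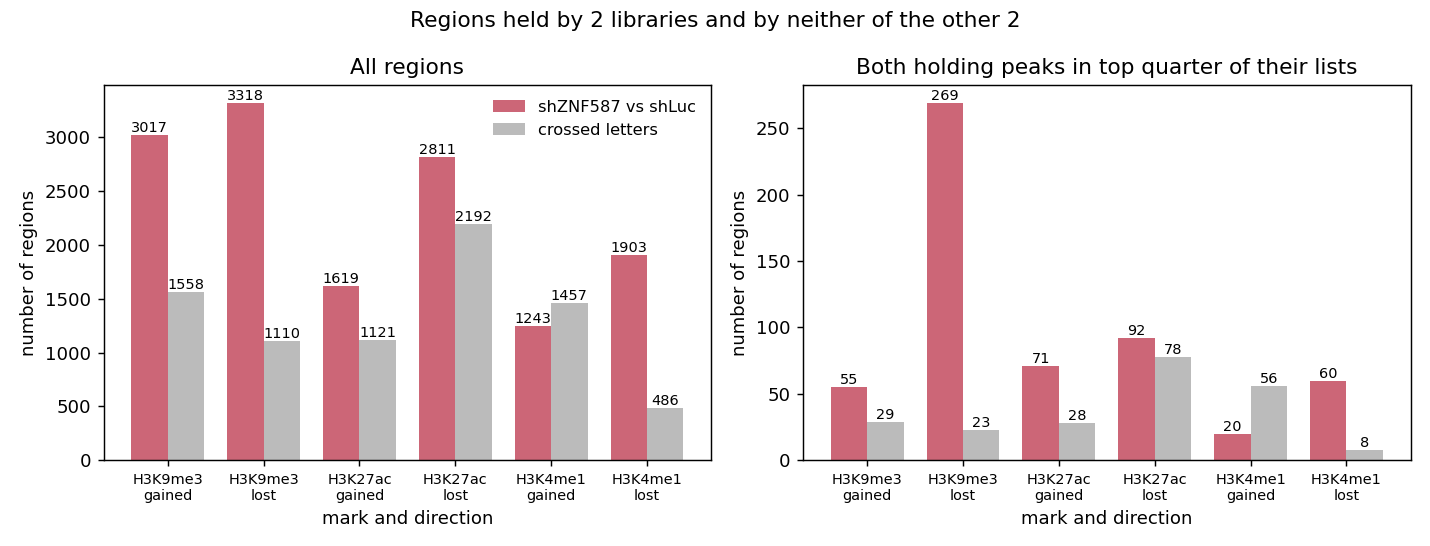
Number of regions held by one pair of libraries and by neither of the other pair, for each mark and direction, under shZNF587 against shLuc (red) and under the crossed division (grey). Left, all regions. Right, regions whose peaks lie above the 75th percentile of both holding lists. H3K9me3 loss stands out on the right with 269 regions against 23.

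H3K27ac differed less from its background. Peaks were gained in shZNF587 at 1619 regions and lost at 2811, with 24413 kept. The lost regions made up 7.84% of those held by both shLuc libraries. The crossed division gave 1121 and 2192, so that the real division held 1.34 times as many one-sided regions. Above the 75th percentile of both lists, 71 regions were gained and 92 lost, against 28 and 78 in the crossed division.

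The H3K27ac gains of best rank lay on chromosome 10 at 22541001–22542000, chromosome 11 at 132614001–132616800, chromosome 12 at 29993201–29996600, chromosome 22 at 48834201–48839200 and chromosome 14 at 88263601–88266400. Further gains were on chromosome 2 at 131792001–131794800, chromosome 1 at 231556601–231558800 and chromosome 13 at 112130801–112133800. The losses were led by chromosome 15 at 32162201–32163600, chromosome 19 at 7681001–7685000, chromosome 16 at 74515601–74519000 and chromosome 16 at 72829201–72832800. Chromosome 14 at 37302401–37307400, chromosome 5 at 24363201–24366000 and chromosome 1 at 46324801–46330800 came next. Of the 12 best-ranked regions, 5 gained and 4 lost held a shE peak.

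Covered length of H3K27ac was 422 ± 146 Mb in shLuc and 359 ± 115 Mb in shZNF587 (SD, n = 2 each, exact permutation p = 0.667). The difference of −63.1 Mb turned to 40.5 Mb without shLuc A and 18.2 Mb without shZNF587 B, and was −167 Mb without shLuc B and −144 Mb without shZNF587 A. The letters set these lists further apart than the groups, with 128381 and 54592 peaks in shLuc A and B, and 115326 and 57066 in shZNF587 A and B. Division by letter gave 397 and 24227 one-sided regions. Within letter A, 23376 regions were held by shZNF587 alone and 38010 by shLuc alone, and within letter B 14527 and 14158. The Jaccard index was 0.459 for the letter A libraries of both groups, 0.373 for the letter B libraries and 0.348 to 0.380 within groups. It was 0.338 for shLuc A with shZNF587 B and 0.362 for shLuc B with shZNF587 A, which differ in letter and group. Gained regions numbered 10152 without shLuc A, 5054 without shZNF587 A and 22770 without shZNF587 B. Lost regions numbered 6100 without shLuc A, 37307 without shLuc B and 11229 without shZNF587 A.

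H3K4me1 peaks were lost in shZNF587 at 1903 regions and gained at 1243, with 48668 kept. Which direction was more frequent depended on the setting. Gains outnumbered losses with 50% of a region covered (3305 against 2356), with equal numbers of top peaks by score (3259 against 2462) or by p or q value (2488 against 1484), and in bins of 1 kb (21528 against 11748). The 1903 lost regions were 2.88% of those held by both shLuc libraries. In the crossed division the one-sided counts were 1457 and 486. The real total was 1.62 times the crossed one (3146 against 1943), and gains alone were fewer than one of the crossed counts. Above the 75th percentile, 60 regions were lost and 20 gained, against 56 and 8 in the crossed division. High-ranking H3K4me1 changes thus stayed near the background.

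The H3K4me1 losses of best rank were on chromosome 16 at 51901601–51902600, chromosome 7 at 155435801–155436600, chromosome X at 136515001–136516800, chromosome 16 at 66536001–66537400, chromosome X at 47033001–47036000 and chromosome X at 54835601–54837200. Of the 12 lost regions named by rank, 11 held a shE peak. The gains were led by chromosome 11 at 81511001–81514000, chromosome 1 at 21828601–21832400, chromosome 6 at 105584001–105586200, chromosome 7 at 4190801–4196800 and chromosome 20 at 55093201–55098600. Of these 12 gained regions, 9 held a shE peak.

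H3K4me1 covered 458 ± 102 Mb in shLuc and 498 ± 68.8 Mb in shZNF587 (SD, n = 2 each, exact permutation p = 0.667). The difference of 39.2 Mb turned to −32.7 Mb without shLuc B and −9.41 Mb without shZNF587 A, and was 111 Mb without shLuc A and 87.8 Mb without shZNF587 B. Division by letter gave 1514 and 25593 one-sided regions. Within letter A, 14599 regions were held by shZNF587 alone and 12754 by shLuc alone, and within letter B 9361 and 24574, so the direction differed between letters. The Jaccard index reached 0.687 for the letter A libraries, against 0.497 and 0.494 within groups. It was 0.485 for shLuc A with shZNF587 B and 0.484 for shLuc B with shZNF587 A, which differ in letter and group. Gained regions numbered 6508 without shLuc A, 2305 without shLuc B, 4120 without shZNF587 A and 12892 without shZNF587 B. Lost regions numbered 8760, 11751, 17431 and 3091 in the same order.

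Changes of different marks met at few loci. Where H3K9me3 was lost, H3K4me1 was gained at 45 regions, while 14.1 would overlap at the rate of kept regions of the same length (odds ratio 3.20, 95% interval 2.20 to 4.65, adjusted p = 3.84e-10, by the exact conditional test 2.93e-08). In the crossed division the odds ratio was 0.974, from 4 loci (95% interval 0.350 to 2.71). The 45 loci were led by chromosome 7 at 140060801–140064000, chromosome 1 at 25929201–25931400, chromosome 7 at 128213801–128217800, chromosome 6 at 31942801–31946200 and chromosome 19 at 29096001–29101600. H3K27ac was gained at 0 of the 45 and lost at 2. The excess rested on the adjustment for length. Without it, 1.36% of lost and 1.03% of kept regions overlapped a gained H3K4me1 region (log2 odds ratio 0.40, Fisher's exact test, adjusted p = 0.191). On the log2 scale the adjusted ratio of 1.68 became 0.96 without shLuc A, 0.42 without shLuc B, 0.37 without shZNF587 A and 1.27 without shZNF587 B. It no longer passed the test without shLuc B. With equal numbers of top peaks by score it was 0.74 and passed.

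The active marks were gained together at 41 H3K27ac regions, against 8.86 at the rate of kept regions (odds ratio 4.76, 95% interval 3.11 to 7.29, adjusted p = 8.17e-15, by the exact conditional test 3.44e-11). The crossed division gave 1.49, from 15 loci (95% interval 0.858 to 2.57). Division by letter, from 10 loci, gave 2.02 (95% interval 1.05 to 3.87, adjusted p = 0.0397, by the exact conditional test 0.0515), which overlaps the interval of the real division. The 41 loci were led by chromosome 9 at 19432801–19437800, chromosome 1 at 94894001–94897800 and chromosome 9 at 97232801–97236200. On the log2 scale the ratio of 2.25 became 0.38 without shLuc A, 1.65 without shLuc B, 1.51 without shZNF587 A and 1.02 without shZNF587 B. It was 0.81 with equal numbers of top peaks by score, and it passed the test each time. H3K27ac and H3K4me1 were lost together at 53 regions, against 25.9 at the kept rate (odds ratio 2.13, 95% interval 1.53 to 2.98, adjusted p = 6.28e-06, by the exact conditional test 3.08e-05). The crossed division gave 1.40 (95% interval 0.608 to 3.21), which overlaps that interval, and division by letter 1.22. Chromosome 1 at 46324801–46330800 and chromosome 1 at 6254601–6266200 ranked first. This result did not hold with equal numbers of top peaks by score (log2 odds ratio −0.11), without shZNF587 A (−0.047) or without length strata (0.30, Fisher's exact test, adjusted p = 0.288). It was 0.46 without shLuc B and 0.57 without shZNF587 B. Inputs, which the labels do not separate by mark, were not analysed here, so differences between them remain open for joint changes.

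Opposite changes of H3K9me3 and H3K27ac did not pass the test. H3K27ac was gained at 24 lost H3K9me3 regions, against 16.6 at the kept rate (odds ratio 1.40, 95% interval 0.875 to 2.23, adjusted p = 0.167, by the exact conditional test 0.195). The first by rank lay on chromosome 12 at 131814001–131816200. For this pair the crossed division gave 0.453, from 2 loci (95% interval 0.111 to 1.84). Division by letter gave 0.262, from 9 loci (95% interval 0.112 to 0.614). H3K27ac was lost at 39 gained H3K9me3 regions, against 29.7 (odds ratio 1.34, 95% interval 0.945 to 1.90, adjusted p = 0.120, by the exact conditional test 0.141), and the crossed division gave a ratio of 1.73 (95% interval 1.11 to 2.71). The first of these ratios passed with equal numbers of top peaks by score (log2 odds ratio 0.88) or by p or q value (0.68), without shLuc A (0.72) and without shZNF587 B (0.71), but turned without shLuc B (−0.37), without shZNF587 A (−0.11) and without length strata (−0.29). The other passed with equal numbers by score (0.60), without shLuc B (0.49) and without shZNF587 A (0.68), was 0.10 without shLuc A and turned without shZNF587 B (−0.080).

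The shE library held more of the lost than of the gained H3K9me3 regions. A shE peak lay in 61.8% of the lost regions (2052 of 3318, exact 95% interval 60.2 to 63.5), in 14.7% of the gained (442 of 3017, 13.4 to 15.96) and in 92.8% of the kept regions. Of the 269 lost regions above the 75th percentile, 89.6% held one. The crossed division gave 28.1% and 17.97%. The division by letter, which ignores the hairpin, gave 56.2% and 8.55%, a gap of 47.6 percentage points against 47.2 under the real division. Within letter A the shares were 32.0% of regions held by shLuc alone and 13.5% of those held by shZNF587 alone, and within letter B 54.4% and 32.4%.

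The other marks showed smaller gaps. For H3K27ac a shE peak lay in 66.2% of lost and 46.9% of gained regions (Fisher's exact p = 5.51e-36 over regions), against 60.5% and 52.7% in the crossed division. For H3K4me1 the shares were 79.1% and 49.3% (Fisher's exact p = 3.58e-67 over regions), against 72.8% and 64.1%. Division by letter gave wider gaps than the hairpin, 34.7 points for H3K27ac and 64.7 for H3K4me1. The shE lists shared most bases with shLuc A, with Jaccard indices of 0.714, 0.505 and 0.707 for H3K9me3, H3K27ac and H3K4me1. The gap between lost and gained regions changed when single libraries were left out, which leaves the letters unbalanced. Without shLuc A it went from 47.2 to −13.4 percentage points for H3K9me3 and from 19.3 to −28.0 for H3K27ac. For H3K4me1 it went from 29.8 to −51.5. Without shLuc B it was 11.6, −7.11 and 12.9, and without shZNF587 A 65.0, 49.4 and 67.9. Without shZNF587 B, H3K27ac gave 35.6. Since division by letter alone gave wide gaps, these values cannot tell whether the gap depends on shLuc A. With equal numbers of top peaks by score the gap for H3K27ac was 1.63 points and no longer passed the test (Fisher's exact p = 0.241). The gap for H3K4me1 was then 11.05 points, and 18.7 with equal numbers by p or q value.

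**Figure D3:**
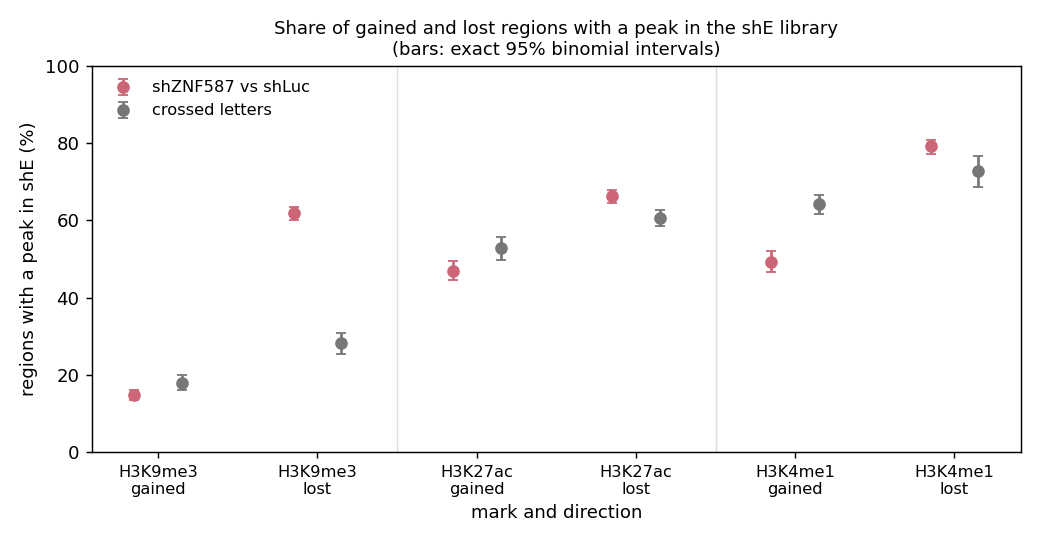
Share of gained and lost regions with a peak in the shE library (%, points) with exact 95% binomial intervals (bars), for shZNF587 against shLuc (red) and for the crossed division (grey). Lost H3K9me3 regions hold a shE peak in 61.8% of cases, against 28.1% in the crossed division. The division by letter, not drawn, gave 56.2%.

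How many chromosomes departed from the distribution of kept regions depended on the setting. Of 138 tests, 8 passed for H3K9me3, 11 for H3K27ac and 2 for H3K4me1, and the crossed division passed 2, 9 and 3. With equal numbers of top peaks by score these counts were 3, 15 and 22, and by p or q value 5, 14 and 11. They were 10, 27 and 19 without shLuc A, 21, 25 and 20 without shLuc B, 16, 25 and 26 without shZNF587 A, and 7, 23 and 26 without shZNF587 B. Chromosome X held 76 of the 3318 lost H3K9me3 regions (2.29%, against 1.48% of kept regions, odds ratio 1.56, Fisher's exact test, adjusted p = 0.00751) and 14 of the 3017 gained (odds ratio 0.310, Fisher's exact test, adjusted p = 2.12e-05). The crossed division had as low a value in 1 direction, with 6 of 1558 regions on X (odds ratio 0.257), and 0.605 in the other, while division by letter gave 5.29 among regions missing in the B libraries. The excess of losses on X was not stable. Its odds ratio was 0.987 with equal numbers of top peaks by score, 1.21 by p or q value and 0.526 in the upper 50% of each list. It was 0.867 without shLuc A, 0.927 without shZNF587 B, 2.59 without shZNF587 A and 4.68 without shLuc B. The deficit of gains on X became 0.897 without shLuc A and an excess of 2.09 without shZNF587 B. Each left-out library leaves the letters unbalanced, and division by letter alone gave 5.29. These left-out values can therefore follow the letter and do not by themselves show instability.

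Chromosome 19, which carries many clustered KRAB zinc finger genes, held few gains of the active marks. It held 1.54% of gained H3K27ac regions, against 4.46% of kept regions (odds ratio 0.336, Fisher's exact test, adjusted p = 4.66e-08), and 1.53% of gained H3K4me1 regions, against 3.69% (odds ratio 0.405, adjusted p = 4.87e-04). The H3K27ac ratio passed in every setting run for single chromosomes, from 0.286 to 0.483. The H3K4me1 ratio was 0.943 without shZNF587 A and no longer passed, and 0.254 without shZNF587 B. In the crossed division, whose directions are arbitrary, the odds ratios on chromosome 19 were 0.569 and 0.613 for H3K27ac and 0.530 and 2.03 for H3K4me1. Each of these passed as well (Fisher's exact test, adjusted p = 0.0210, 0.00301, 0.00432 and 0.00432). One-sided H3K27ac regions were thus fewer on chromosome 19 without the hairpin contrast too. The chromosome tests were not stratified by length, and gained H3K27ac regions had a median of 4400 bp, against 10800 bp for kept regions. Lost H3K9me3 regions were fewer on chromosome 19 than kept ones (odds ratio 0.686, Fisher's exact test, adjusted p = 0.0308), and the crossed division gave 0.344 and 1.10. The ratio of 0.686 no longer passed without shZNF587 B (0.875), with peaks up to 1 kb apart merged (0.695) or with shE required to look like shLuc (0.696), and was 0.444 without shLuc B. Gained H3K9me3 regions were more frequent there (odds ratio 1.35, Fisher's exact test, adjusted p = 0.0356), but the ratio was 0.740 without shLuc A, 0.831 without shZNF587 B and 0.707 in bins of 1 kb. It was 1.14 with 50% of a region covered, 1.15 with equal numbers of top peaks by score, 0.766 in the upper 50% of each list and 1.34 with shE required to look like shLuc, and passed in none of these 4 settings.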

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

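The settings with peaks above a percentile, with equal numbers of top peaks by p or q value, with wide peaks left out, and the exact conditional test, and all alternatives for the shE and chromosome results and the named regions were chosen after seeing the data, as were the left-out libraries for the Jaccard index and covered length. Across 223 comparisons of results with alternatives, 118 stayed within the limits set for them, 82 moved, 9 newly passed a test, 4 no longer passed and 10 changed direction. Differences with no test, in Jaccard index or covered length, changed sign in 9 cases, which are counted among those that stayed or moved. Of the named regions, 8 to 12 of the 12 lost H3K9me3 regions and 10 to 12 of the gained were called again under each setting, but as few as 4 lost H3K27ac and 3 gained H3K4me1 regions. The ratio of one-sided regions in the real to the crossed division was 1.57 to 2.39 for H3K9me3, 1.06 to 1.39 for H3K27ac and 1.13 to 1.62 for H3K4me1. Unknown read depth limits all counts. Gene lists and their alternative windows were not run, since no hg19 annotation was used here. Unless the construction of a setting shows it, the cause was not tested.

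With 50% of a region covered, H3K9me3 gains numbered 4814, above its 4104 losses, H3K27ac losses 4950 and H3K4me1 gains 3305, above its 2356 losses. Bins of 1 kb count long regions many times and gave 18087 gains and 15807 losses for H3K9me3, 16243 and 37667 for H3K27ac, and 21528 and 11748 for H3K4me1. In the upper 50% of each list, H3K4me1 had 2127 gains and 3579 losses. Requiring shE to look like shLuc, which can only remove regions, left 2052 H3K9me3 losses, 860 and 1860 H3K27ac gains and losses, and 630 H3K4me1 gains. Peaks above the 50th percentile of both lists left 296 gains and 759 losses for H3K9me3, 286 and 411 for H3K27ac, and 136 and 233 for H3K4me1. Above the 75th percentile these were 55 and 269, 71 and 92, and 20 and 60.

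With equal numbers of top peaks by score, H3K4me1 gains numbered 3259 and losses 2462. The log2 odds ratio was 0.88 for H3K27ac gains and 0.60 for H3K27ac losses at H3K9me3 losses and gains, both newly past the test, and −0.11 for joint losses of the active marks, a change of direction. The H3K27ac gap in shE peaks was 1.63 points. Chromosome tests passed numbered 3 for H3K9me3 and 22 for H3K4me1, and the Jaccard difference within minus between groups was −0.0225 for H3K4me1. By p or q value, H3K4me1 gains numbered 2488 and losses 1484, the log2 odds ratio of H3K27ac gains at lost H3K9me3 was 0.68, 5 and 11 chromosome tests passed for H3K9me3 and H3K4me1, and the Jaccard differences were 0.00318 for H3K27ac and −0.0287 for H3K4me1. Without length strata, the log2 odds ratio of H3K4me1 gains at lost H3K9me3 was 0.40 and that of joint losses of the active marks 0.30, neither past the test, and H3K27ac gains at lost H3K9me3 turned to −0.29.

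A replicate block by letter asks for a difference within a pair only, so its mean counts are larger by construction. The paired means were 17588 gains and 17247.5 losses for H3K9me3, 18951.5 and 26084 for H3K27ac, and 11980 and 18664 for H3K4me1. Paired log2 odds ratios of 0.20 for H3K27ac gains at lost H3K9me3 and 0.34 for H3K27ac losses at gained H3K9me3 passed the test, and the block changed no other call. The difference A minus B in shLuc correlated with that in shZNF587 over regions by 0.176 for H3K9me3, −0.0123 for H3K27ac and 0.335 for H3K4me1. The labels do not say that the letters mark a batch, and there are only 2 pairs, so the letters were not taken as pairing the libraries.

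Leaving out each library in turn asks for fewer libraries and leaves the letters unbalanced. Changes under these settings, also for single chromosomes and pairs of marks, can therefore follow the letter. Gains then ranged from 4518 to 15603 and losses from 4300 to 15588 for H3K9me3, from 2199 to 22770 and 4067 to 37307 for H3K27ac, and from 2305 to 12892 and 3091 to 17431 for H3K4me1. The log2 odds ratio ranged from −0.37 to 0.72 for H3K27ac gains and 0.37 to 1.27 for H3K4me1 gains at lost H3K9me3, −0.080 to 0.68 for H3K27ac losses at gained H3K9me3, and −0.047 to 1.36 for joint losses. The gap in shE peaks ranged from −13.4 to 65.0 points for H3K9me3, −28.0 to 49.4 for H3K27ac and −51.5 to 67.9 for H3K4me1. Chromosome tests passed ranged from 7 to 21, 23 to 27 and 19 to 26, and Jaccard differences from −0.0619 to 0.0374, −0.0507 to 0.0238 and −0.0918 to −0.000924. The difference in covered length ranged from −68.9 to 82.5 Mb for H3K9me3, −167 to 40.5 Mb for H3K27ac and −32.7 to 111 Mb for H3K4me1.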

Other observations

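Lost H3K9me3 regions had a median length of 2400 bp and gained regions of 2800 bp, while kept regions measured 5000 bp. The crossed division gave 2200 and 2800 bp, and division by letter 2600 and 3000 bp. Short one-sided regions were thus not particular to the hairpin contrast. Chromosome 3 held 8.03% of gained H3K27ac regions, against 5.67% of kept regions (odds ratio 1.45, Fisher's exact test, adjusted p = 0.00426), with crossed odds ratios of 1.09 and 1.11. This did not pass with 50% of a region covered (1.26), with equal numbers of top peaks by score (1.24), with peaks up to 1 kb apart merged (1.32), in the upper 50% of each list (1.26) or with shE required to look like shLuc (1.36). Chromosome 16 held 5.52% of lost H3K4me1 regions, against 3.95% (odds ratio 1.42, Fisher's exact test, adjusted p = 0.0103), with crossed odds ratios of 0.775 and 1.10. It turned to 0.725 without shLuc B, 0.803 without shZNF587 A, 0.853 with equal numbers of top peaks by score and 0.878 in the upper 50% of each list, and did not pass with equal numbers by p or q value (1.18). Chromosome 18 was over-represented among gained and lost H3K27ac regions (odds ratios 1.71 and 1.71), but also in the crossed division (2.04 and 1.48). The gains there did not pass in the upper 50% of each list (1.198) or with shE required to look like shLuc (1.67). Neighbouring regions shared a change somewhat more often than in shuffles. The nearest neighbour of a lost H3K9me3 region was lost in 3.83% of cases, against a median of 2.88% in 1000 shuffles (permutation p = 0.00899), and over the 6 sets of gained and lost regions p ranged from 0.001, the smallest that shuffles can give, to 0.0360. The longest run of lost H3K9me3 regions held 4. A share above the highest shuffle had been asked for beforehand, which the H3K9me3 sets did not reach, but that bound is stricter than the permutation test.

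The tests of peak numbers, of the H3K27ac share on X and of the odds ratio in the crossed division were chosen only after the result was seen. H3K9me3 peaks that ranked high by score in both shLuc libraries, 269 above the 75th percentile, were without a call in both shZNF587 libraries. Fewer calls in both hairpin libraries are argued against, because these held as many peaks as the control of their letter (lower ratio 1.004). Equal numbers of calls do not show equally strong calls. Peaks with a deposited p-value or q-value of 0 made up 2.04% of the shZNF587 A list, against 2.70% for shLuc A. For shZNF587 B they made up 0.761%, against 1.06% for shLuc B. Scores of 0 were more frequent in shZNF587, 7.88% against 3.13% in letter A and 0.117% against 0.0028% in letter B. A depth ratio of ChIP over input was fitted to each list, taking the deposited p-value or q-value as a Poisson tail. It was lower in shZNF587, 0.383 against 0.4595 in letter A and 0.698 against 0.771 in letter B. How strongly the libraries were enriched, and how deeply they were sequenced, was not tested and stays open. The covered length of the hairpin libraries was 1.07 times that of the control in letter A and 0.945 times in letter B. Fewer called bases in letter B alone cannot by themselves account for calls that were also missing in shZNF587 A. A deleted stretch of chromosome would remove neighbouring regions together, yet the nearest neighbour was also lost at 3.82% of the lost regions above the 50th percentile. An effect of the hairpin was not tested apart from these, and differences between inputs, not analysed here, or between separate cultures remain open.

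Gained H3K4me1 at lost H3K9me3 regions was weighed against chance and against a peculiarity of shLuc. If weak regions of both lists flipped by chance, the crossed division would show the same excess. Its odds ratio was 0.974, below the real 95% interval of 2.20 to 4.65. It rests on 4 loci, with a 95% interval of 0.350 to 2.71. The difference between the divisions was not tested, so chance flips stay open. If shLuc alone carried H3K9me3 there, shE would lack it, and 86.7% of the 45 loci (39, exact 95% interval 73.2 to 94.9) held an H3K9me3 peak in shE, while 28.9% held an H3K4me1 peak. Over all lost H3K9me3 regions the share with a shE peak was 61.8%, and over all gained H3K4me1 regions 49.3%. What shE targets is not known, and its list was closest to shLuc A. The look-up therefore shows only that shE resembled shLuc at most of these loci. The excess also rests on the length strata, without which the log2 odds ratio of 0.40 did not pass.

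The excess of lost H3K9me3 regions on chromosome X was weighed last. Weak calls that flip by chance would give an excess in the crossed division as well, where the odds ratio of X was 0.402 among all one-sided regions and 0.605 among losses (95% interval 0.323 to 1.13), against 0.959 and 1.56 in the real division. Division by letter gave 5.001 and 5.29, so calls on X differed strongly between letters. Fewer copies of X would lower its share in every mark, and the share of peaks on X in shZNF587 over shLuc was at least 1.12 for H3K27ac but 0.978 and 0.911 for H3K4me1, which leaves this open. The share of H3K9me3 peaks on X was lower in both letters (ratios 0.877 and 0.730). This share comes from the same lists as the lost regions, so it cannot tell a general shortage of X calls from the excess itself. With equal numbers of top peaks by score the odds ratio for losses on X was 0.987.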
